A study of Homo sapiens with 21 samples.

How the data were processed

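Gene expression was measured by polyA-selected RNA sequencing in 21 libraries from 7 human pancreatic ductal adenocarcinoma cell lines. Each line gave 1 control library, 1 library after A485 and 1 library after SAHA, so no line was sequenced more than once in a condition. Per the labels' protocols, Capan-1 and Capan-2 were grown in RPMI medium with 20% serum, and Colo357, PaTu-S, MIA PaCa-2, PANC1 and PaTu-T in DMEM with 10% serum. The protocols describe treatments of 24 and 96 hours and of 4 to 30 weeks, and the labels do not say which of them applied to these libraries.

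The values analysed are the raw counts per gene deposited by the authors, in a table of whole numbers without normalization. Per the submitters' processing notes, STAR 2.7.3a and genome build GRCh38 were used. The notes do not give the annotation, the program that counted reads or the strand setting, so counts in overlapping and antisense genes are uncertain. The table holds 54456 Ensembl gene IDs, of which 54246 have a symbol. IDs without a symbol hold 0.026% of the counts. Coordinates were taken from GENCODE 29 and matched 52387 IDs. No count was found in any library for 15186 genes.

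Total counts per library ran from 11518316 to 21824683, which sets the precision of each value. Floors for genes with no count were set at 3 counts, and floors and counting intervals cover counting error only. In models with cell line as a block, p-values measure how far a change varies between lines, together with noise between libraries. In the control libraries they measure the spread between lines. None measures the spread between repeats of the same line, since each line and condition has 1 library.

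Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, genes with low counts were removed by filterByExpr on the 3 conditions, and a quasi-likelihood model with robust dispersion was fitted with cell line as a block. This left 15805 genes in the fit of all 21 libraries. A485 against control, SAHA against control and SAHA against A485 were tested within lines by the edgeR quasi-likelihood test. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called.

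The labels give line names and no subtype of each line. A set E (Capan-1, Capan-2, Colo357 and PaTu-S, commonly described as epithelial) and a set M (MIA PaCa-2, PANC1 and PaTu-T, commonly described as mesenchymal-like) were fixed from general knowledge of these lines, not from the labels. The sets were compared in the 7 control libraries, over 15177 genes, and by the interaction of line set with each treatment in the fit of all libraries.

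A total of 27 gene lists, written before the counts were seen, were tested against all other genes with limma 3.58.1 camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg over the lists. Camera with a correlation estimated from the data and fry were run beside it. Member counts are given over all genes tested and adjusted over the list alone.

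The size of each line's response was the root mean square of the log2 ratios of treated over control CPM, with a prior count of 2, over the 15325 genes with a mean count of 10 or more. E and M lines were compared by a two-sided exact permutation test over 35 splits. The relation of the A485 and SAHA changes was measured by Pearson's r across genes, beside 20 simulated pairs of unchanged groups set against the same controls, and beside 70 splits of the lines that removed the shared control.

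Genes were named by a rule written before the counts were seen. EP300, CREBBP, HDAC1, HDAC2, HDAC3, MYC, CDKN1A, CDH1, VIM, ZEB1, GATA6 and KRT19 are always named, and 1 further item of the rule is not reported here. To these were added, in each treatment comparison, the 8 largest called rises and the 8 largest called falls with an average log2 CPM of 2 or more and the same direction in all 7 lines. Here and below, any difference in log2 CPM counted as a direction in a line, even at very few counts. In the control libraries the rule took the 8 largest differences in each direction without overlap between the sets, and for differences between line sets in a treatment effect the 5 largest in each direction without overlap. Clone-based names, LINC numbers and genes without a symbol were not named. Up to 4 called members with the smallest p were named for each list.

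Alternatives were DESeq2 size factors, no filter on low counts, a mean count of 10 or more, leaving out the 2 RPMI lines, no replicate block, only the 14 libraries compared, a fold change of at least 2, the DESeq2 1.42.0 Wald test, limma-voom, and leaving out each line in turn. Removing the trend of each library with GC content, scaling on a list of housekeeping genes and leaving out each line for the response size were added after seeing the data. For each model across genes, other splits of the same libraries were fitted as well. The models were also tested on simulated data built from the real libraries. There, 85% of genes with a 2-fold treatment effect and 98% of those with a 4-fold effect were called, and 3.2% of the calls were false. For the interaction these shares were 25%, 76% and 7.3%. For the 7 control libraries 0% of genes with a 2-fold and 8% of those with a 4-fold difference were called. Each simulation was run once, with changed genes at a mean count of 10 or more. The effect was equal in all lines that received it, and the spread depended only on the level of a gene. Real changes varied between lines, so these shares may be too favourable. Variants, splicing and non-polyadenylated RNA were not analysed here.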

Results

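RNA sequencing covered 7 human pancreatic ductal adenocarcinoma lines, Capan-1, Capan-2, Colo357, PaTu-S, MIA PaCa-2, PANC1 and PaTu-T, each with 1 control library, 1 library after A485 at 1 µM and 1 library after SAHA at 0.5 µM. A485 inhibits the catalytic domain of the acetyltransferases EP300 and CREBBP, and SAHA (vorinostat) inhibits histone deacetylases broadly. Total counts per library ran from 12832708 to 20097676 in controls, 11706012 to 21824683 with A485 and 11518316 to 17768422 with SAHA. The lowest total was that of MIA PaCa-2 with SAHA and the highest that of PaTu-S with A485. Mitochondrial genes took 1.3 to 4.96% of counts. All 21 libraries correlated best with a library of their own line, at r of 0.968 or more across genes, against at most 0.897 with another line (genes are not independent replicates). Capan-1, Capan-2, Colo357 and PaTu-S, commonly described as epithelial, are called E lines below, and MIA PaCa-2, PANC1 and PaTu-T, commonly described as mesenchymal-like, M lines; the sets come from general knowledge and not from the labels. The labels state neither the length of treatment nor whether it was the short or the long protocol. For MIA PaCa-2 the label gives SAHA at 0.5 µM, whereas the protocol gives 0.05 µM for long treatment of that line.

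The first comparison asked which genes change when EP300 and CREBBP are inhibited. EGR1, an immediate early transcription factor, rose 3-fold with A485 (log2 change 1.59 ± 0.16 SE, adjusted p = 2.58e-05) in 7 of 7 lines. NAB2, a corepressor that binds EGR proteins, rose 1.94-fold in all 7 lines (0.96 ± 0.2, adjusted p = 0.00657). ALPP, placental alkaline phosphatase, was 5.27-fold lower (log2 change -2.40 ± 0.33, adjusted p = 0.000381), CREB3L3, a membrane-bound transcription factor of liver and gut, 4.56-fold lower (-2.19 ± 0.4, adjusted p = 0.00292), and the netrin receptor gene UNC5B 4.23-fold lower (-2.08 ± 0.33, adjusted p = 0.00104). CREB3L3 was filtered out without Colo357, whose control held 133 CPM against at most 0.767 CPM in the controls of the other 6 lines. SGK2, ABCA12, KRT15, MUC3A and CD22, which encode a kinase, a lipid transporter, a keratin, a membrane mucin and a lectin, fell by 1.72 to 1.88 on the log2 scale. REEP2, FNDC4, ICA1L, FBLN5, SHISA4 and COCH rose by 1.04 to 1.57 on that scale. FBLN5, an elastic fibre gene, was not called without Capan-2 (adjusted p = 0.0673), PaTu-S (0.0795), MIA PaCa-2 (0.106) or PANC1 (0.0527), nor CD22 without Capan-2 (0.0893). EGR1 (ENSG00000120738) lies on GRCh38 chromosome 5 from 138465490 to 138469315, and ALPP (ENSG00000163283) on chromosome 2 from 232378534 to 232382889. ALPP is nearly identical to its neighbour ALPG, so the assignment of reads between them is uncertain.

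The proto-oncogene MYC fell 1.76-fold with A485 (log2 change -0.82 ± 0.19, adjusted p = 0.0166) in 6 of 7 lines. The cell cycle inhibitor gene CDKN1A fell 1.8-fold in 6 of 7 lines (-0.85 ± 0.2, adjusted p = 0.0142), and the epithelial keratin gene KRT19 1.92-fold in 6 of 7 (-0.94 ± 0.21, adjusted p = 0.0133). CDH1, the gene of E-cadherin, fell 2.11-fold in all 7 lines (-1.08 ± 0.26, adjusted p = 0.0215). MYC (ENSG00000136997) lies on chromosome 8 from 127735434 to 127741434 and CDH1 (ENSG00000039068) on chromosome 16 from 68737225 to 68835548. The targets of the drug did not pass the test: EP300 had a log2 change of 0.33 (adjusted p = 0.153) and CREBBP of 0.26 (adjusted p = 0.292). HDAC1, HDAC2 and HDAC3 had 0.10, -0.02 and 0.13 (adjusted p 0.643, 0.948 and 0.589), VIM -0.15 (0.855), ZEB1 -0.02 (0.982) and GATA6 -0.56 (0.259). The calls of MYC, CDKN1A, KRT19 and CDH1 were each lost when certain single lines were left out. MYC was not called without Colo357 (adjusted p = 0.0664), PaTu-S (0.0768) or PaTu-T (0.0551), CDKN1A without Colo357 (0.0578) or PANC1 (0.0684), KRT19 without PaTu-S (0.0543) or PANC1 (0.0705), and CDH1 without MIA PaCa-2 (0.0584) or PANC1 (0.0566).

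Over all genes, 640 of 15805 changed with A485, 102 up and 538 down, so 15.9% of the calls were rises. A total of 79 rose and 222 fell in all 7 lines. Among the 283 with at least a 2-fold change, 17 were up and 266 down. The count was 1283 with no filter on low counts and 998 with limma-voom. With the GC trend removed, chosen after seeing the data, it was 1116, with 25.5% rises. It was 326 without PaTu-S, 364 without Capan-2 and 215 without both lines grown in RPMI. Without those lines NAB2 (adjusted p = 0.107), SGK2 (0.1), ICA1L (0.0977), FBLN5 (0.0883), COCH (0.0636), SHISA4 (0.0581), ABCA12 (0.0556), UNC5B (0.0552), CDKN1A (0.0701) and CDH1 (0.0937) were not called. Of the genes named in the lists below, neither were MUC5AC (0.0889), MUC13 (0.0554), S100A4 (0.0622), FDFT1 (0.0554) and TGFB2 (0.0872), among others. With no replicate block for the line, edgeR called 0 genes, with 55 at an unadjusted p under 0.05.

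**Figure D1:**
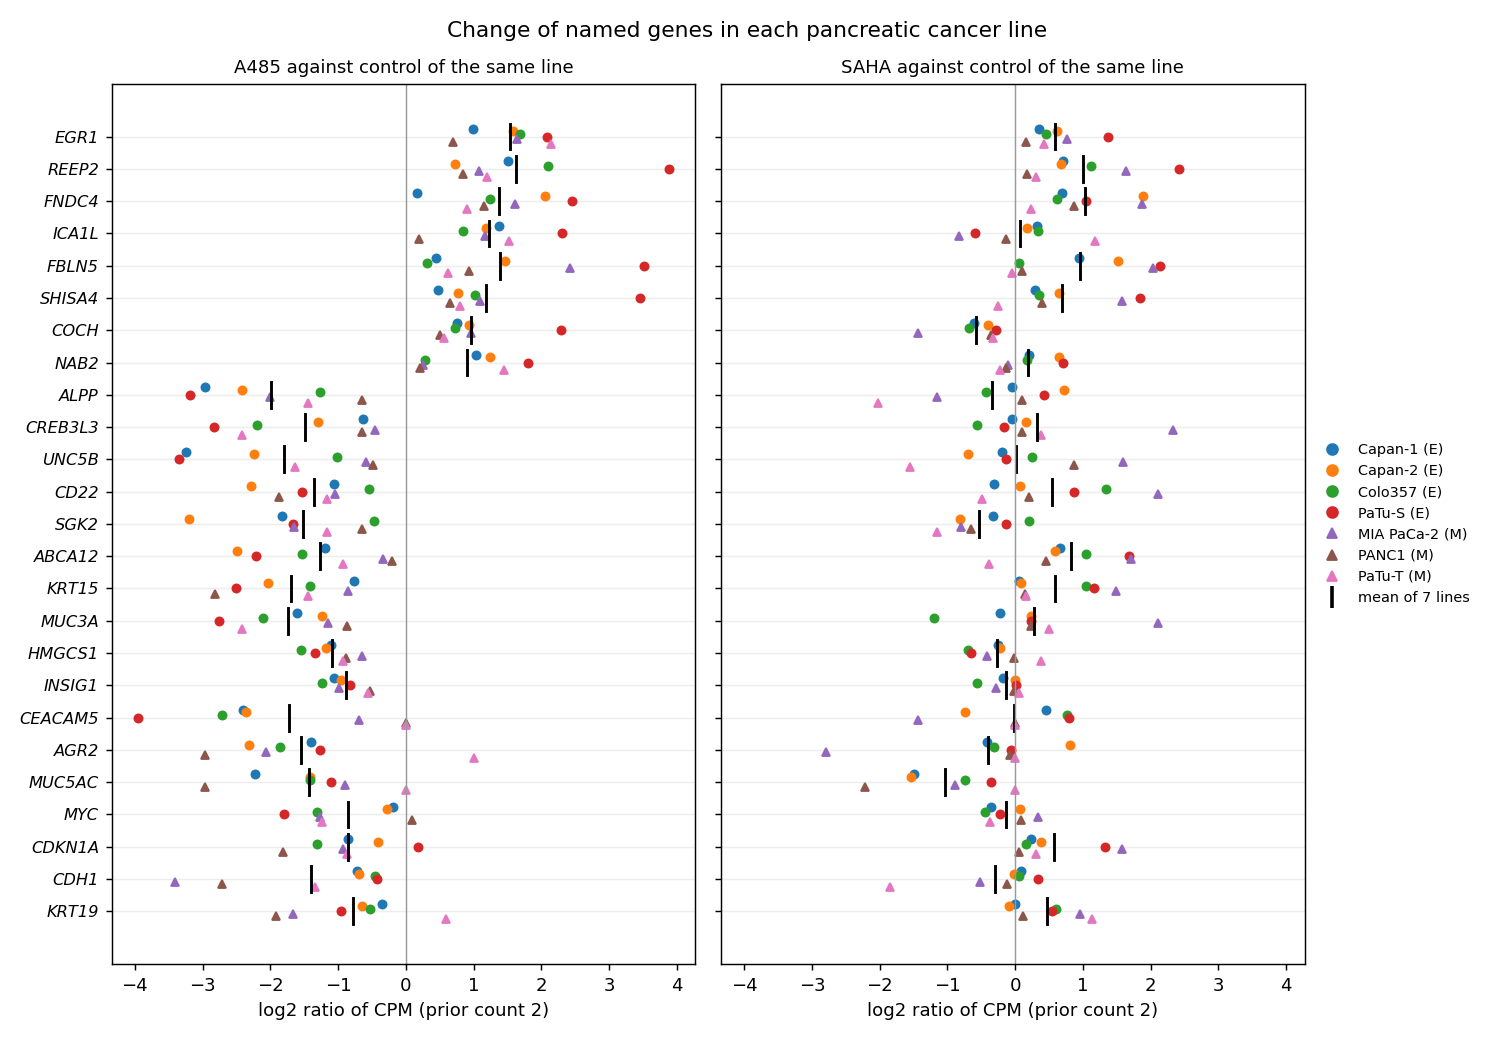
Log2 ratio of treated over control CPM of the same line (prior count 2) for named genes, with A485 on the left and SAHA on the right; circles are the 4 E lines, triangles the 3 M lines and the bar the mean of 7 lines. EGR1 lies above 0 in all 7 lines with A485 and HMGCS1 below 0 in all 7.

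Several gene groups fell together with A485. The classical tumour signature, the secretory and gut-like programme of pancreatic cancer, had 19 of 26 tested genes down and none up (25 down adjusted over the list alone), with a median log2 change of -1.40. CEACAM5, a surface glycoprotein gene, was 7.84-fold lower (-2.97 ± 0.38, adjusted p = 0.000432), AGR2, a secretory folding factor gene, 3.76-fold lower (-1.91 ± 0.29, 0.000781), GPX2 3.6-fold lower (-1.85 ± 0.27, 0.000633) and PRR15L 3.27-fold lower (-1.71 ± 0.23, 0.000322). CEACAM5 fell in 5 lines and had no count with A485 or in the control in PANC1 and PaTu-T. AGR2, GPX2 and PRR15L fell in 6 lines. The median of the list lay between -1.54 and -1.03 in Capan-1, Capan-2, Colo357, PaTu-S and MIA PaCa-2, and at 0 in PANC1 and PaTu-T. A gene with no count in either library has a ratio of 0. In the controls the list had a median log2 difference of M minus E lines of -8.56. The medians at 0 therefore do not show that A485 spared these genes. Among mucin genes, 4 of 9 fell (7 adjusted over the list alone). These were MUC3A, the gel-forming MUC5AC (-1.83 ± 0.3, adjusted p = 0.00149), and the membrane mucins MUC13 (-1.71 ± 0.3, 0.00292) and MUC16 (-1.83 ± 0.41, 0.0133). MUC16 was not called without Capan-1 (0.0698) or PANC1 (0.0569). Camera called both lists lower (adjusted p = 2.19e-25 and 2.22e-07), and with an estimated correlation the adjusted p was 0.0202 for the classical signature and 0.0497 for the mucins.

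With A485 the median change of cholesterol synthesis genes lay below 0 in every line. A485 lowered 14 of 25 and raised none (18 lower adjusted over the list alone), with a median log2 change of -0.47 and line medians from -0.60 to -0.35. HMGCS1, which makes the HMG-CoA used for sterols, fell 2.14-fold (-1.10 ± 0.12, adjusted p = 6.02e-05), and INSIG1, which restrains the sterol-sensing transcription factors, fell 1.85-fold (-0.88 ± 0.1, 4.65e-05). The squalene enzymes SQLE and FDFT1 fell by 0.68 and 0.54 on the log2 scale (adjusted p = 0.00153 and 0.00176). All 4 fell in 7 of 7 lines. HMGCS1 (ENSG00000112972) lies on chromosome 5 from 43289395 to 43313512. The list had a camera adjusted p of 1.19e-21, and an adjusted p of 0.00717 with an estimated correlation.

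In the basal-like tumour signature, 4 of 14 genes fell (5 down and 1 up adjusted over the list alone): the keratin gene KRT15, FGFBP1 (-1.53, adjusted p = 0.018), FAM83A (-0.98, 0.0407) and UCA1 (-0.84, 0.0461). FGFBP1 was not called without PaTu-S (0.0583) or MIA PaCa-2 (0.0569), and FAM83A and UCA1 were each lost without several single lines, at adjusted p up to 0.126 and 0.262. The list was called lower (adjusted p = 0.001, and adjusted p = 0.0497 with an estimated correlation). Of 12 drug efflux transporter genes, ABCC3 (-1.27, 0.00166), ABCG2 (-1.04, 0.00536) and ABCC4 (-0.60, 0.0064) fell (4 down adjusted over the list alone). That list had an adjusted p of 0.00306, and an adjusted p of 0.0745 with an estimated correlation. MYC and NOLC1, a nucleolar chaperone gene, were the 2 genes of 33 that fell among MYC targets and ribosome biogenesis genes (9 adjusted over the list alone; median -0.28, adjusted p = 2.23e-07, adjusted p = 0.354 with an estimated correlation).

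Some epithelial and some mesenchymal genes fell with A485, and these lists were not tested against each other. Among 30 epithelial junction and keratin genes, KRT19, CDH1 and the transcription factor gene ELF3 fell (3 adjusted over the list alone; median -0.27, adjusted p = 0.000373, adjusted p = 0.198 with an estimated correlation). ELF3 (adjusted p = 0.0297) was not called without Capan-1 (0.111), Capan-2 (0.0674), PaTu-S (0.149) or MIA PaCa-2 (0.0584). Among 20 mesenchymal genes, TGFBI, an extracellular matrix protein gene, fell 3.02-fold (-1.59 ± 0.22, adjusted p = 0.000333) and S100A4 1.42-fold (-0.50 ± 0.11, 0.00804), both in 7 of 7 lines (2 adjusted over the list alone; list adjusted p = 0.0189, and adjusted p = 0.124 with an estimated correlation). The quasi-mesenchymal signature had AHNAK2 (-0.99, 0.00771) and FERMT1 (-0.69, 0.00952) down of 15 genes, with the same 2 adjusted over the list alone. FERMT1 was not called without Capan-2 (0.0673). That list had an adjusted p of 0.0189, an adjusted p of 0.194 with an estimated correlation, and was not called without MIA PaCa-2 (0.138) or PaTu-T (0.0737).

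Interferon genes and metallothioneins were the lists called higher with A485. MX1, an interferon-induced antiviral GTPase gene, rose 1.82-fold (log2 change 0.86, adjusted p = 0.0309, higher in 6 of 7 lines), as the only 1 of 31 interferon genes over all genes and as 1 of 5 adjusted over the list alone. MX1 was not called without Capan-2 (0.198), PaTu-S (0.118), MIA PaCa-2 (0.0677) or PANC1 (0.0707). The interferon list had 28 of 31 changes above 0 and an adjusted p of 1.37e-05, and an adjusted p of 0.221 with an estimated correlation. MT2A, a metal-binding protein gene, rose 2.16-fold (1.11 ± 0.28, adjusted p = 0.0255) as 1 of 6 metallothioneins (1 adjusted over the list alone), and was not called without Capan-1 (0.0535), Capan-2 (0.113), MIA PaCa-2 (0.061) or PANC1 (0.0775). That list had an adjusted p of 0.0283, an adjusted p of 0.482 with an estimated correlation, and was not called without MIA PaCa-2 (0.0611) or PANC1 (0.186). Among markers of other cell types, PECAM1 (-1.77, adjusted p = 0.00874) and LAPTM5 (-1.49, 0.0376) fell of 3 tested blood and endothelial genes (2 adjusted over the list alone; list adjusted p = 0.0108, adjusted p = 0.0666 with an estimated correlation). PECAM1 was not called without Colo357 (0.0837), and LAPTM5 without any single line but Capan-1, at adjusted p up to 0.136.

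The other 15 lists were not called. HDAC9 fell (-0.82, adjusted p = 0.0175, 7 of 7 lines) among 26 acetylation writers and erasers, and was not called without PANC1 (0.0508). TP53I3 rose by 0.52 (0.0107) among 25 p53 targets and cyclin-dependent kinase inhibitors, while CDKN1A and GADD45A (-0.90, 0.0283) fell. IGFBP3 (-1.19, 0.00076) and TGFB2 (-1.11, 0.00728) fell and CCN1 rose (0.81, 0.0365) among 22 YAP and TAZ targets. IL32 fell (-0.82, 0.0461) among NF-kappaB and cytokine genes, UNC13A (-1.68, 0.0199) among neuronal genes, and the transferrin receptor gene TFRC (-0.82, 0.00129, 7 of 7 lines) among housekeeping genes. Counts adjusted over each list alone were 1, 1 up and 2 down, 1 up and 2 down, 2 down, 2 up and 3 down, and 1 in the order acetylation, p53, YAP and TAZ, NF-kappaB, neuronal and housekeeping. Without single lines, calls ended for TP53I3 and UNC13A (Capan-2, 0.0505 and 0.0561, with UNC13A filtered out without Capan-1 or PaTu-S), GADD45A (up to 0.0889 without PANC1), CCN1 (up to 0.147 without Capan-2) and IL32 (up to 0.177 without PaTu-S). The list tests gave adjusted p of 0.303 for acetylation genes, 0.119 for bromodomain readers, 0.303 for polyadenylated histone genes, 0.084 for S phase, 0.207 for G2/M, 0.685 for p53 targets, 0.197 for MHC class I, 0.328 for NF-kappaB, 0.685 for hypoxia and glycolysis, 0.084 for the unfolded protein response, 0.886 for the BCL2 family, 0.224 for YAP and TAZ targets, 0.658 for neuronal genes, 0.224 for the 2 tested acinar and endocrine genes and 0.658 for housekeeping genes. For the p53 list the mean was -0.01, against a median of 0.03 and a test direction of up.

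**Figure D2:**
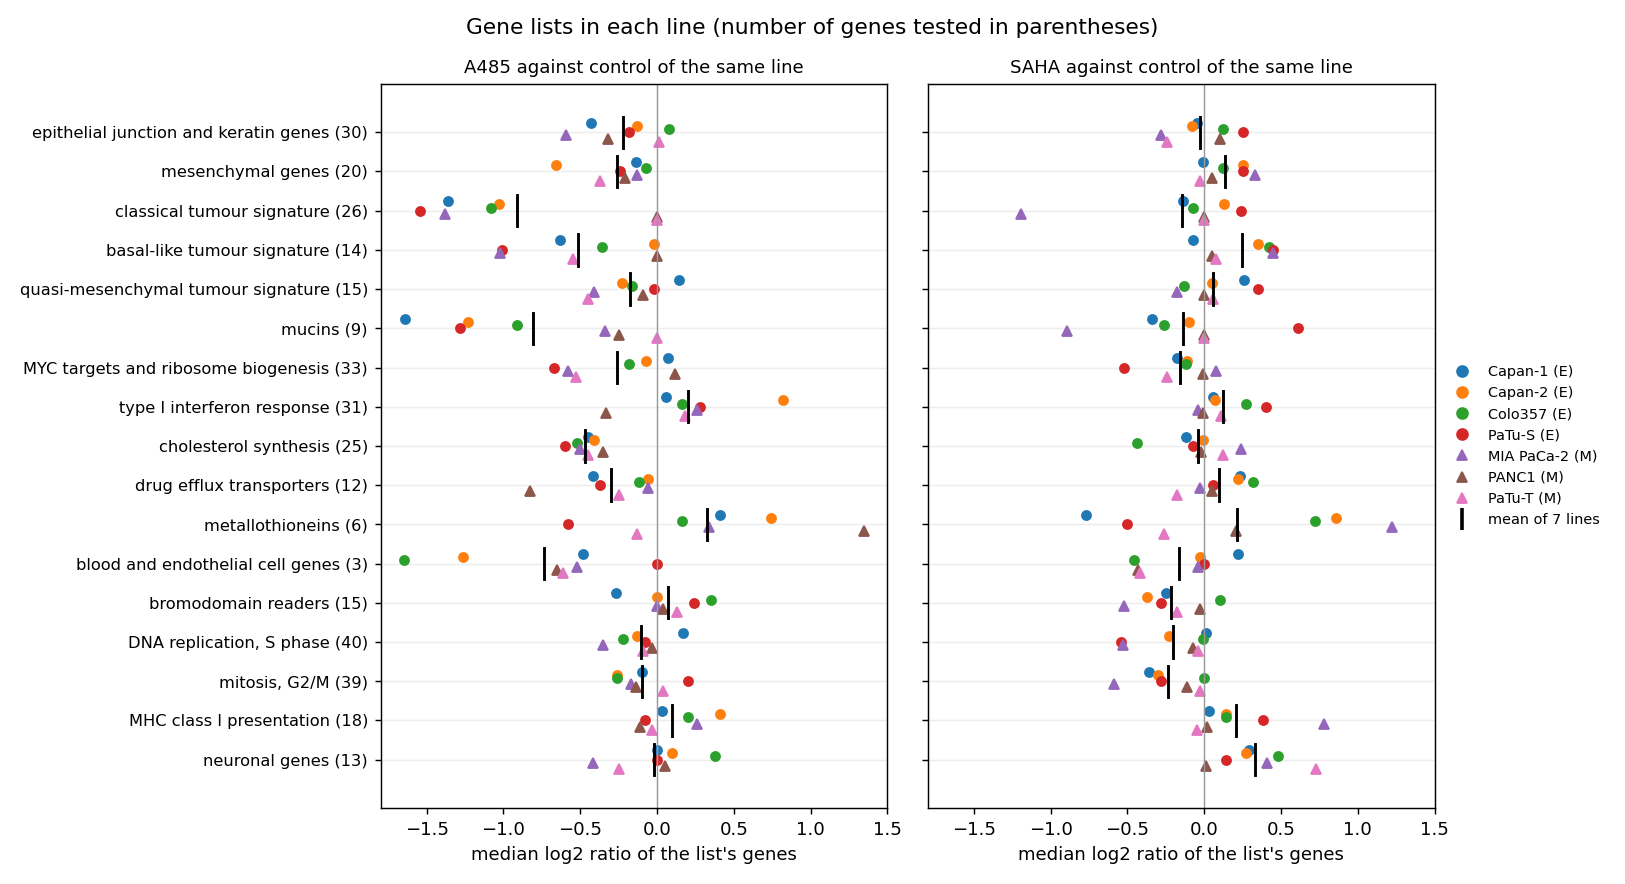
Median log2 ratio of treated over control for the genes of each list in each line, with A485 on the left and SAHA on the right; circles are the 4 E lines, triangles the 3 M lines and the bar the mean of 7 lines. Cholesterol synthesis lies below 0 in all 7 lines with A485, and the classical signature lies at -1.19 with SAHA in MIA PaCa-2.

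The next comparison asked what deacetylase inhibition by SAHA changed. MAPT, the gene of the microtubule protein tau, was 2.09-fold higher with SAHA (log2 change 1.06 ± 0.19 SE, adjusted p = 0.0391), TUBA1A, an alpha tubulin gene, 1.63-fold higher (0.70 ± 0.13, 0.0391), CYFIP2, an actin regulator gene, 2.1-fold higher (1.07 ± 0.17, 0.0203), and APLP1, an amyloid precursor-like protein gene, 2.46-fold higher (1.30 ± 0.24, 0.0423). All 4 rose in 7 of 7 lines. FKBP11, an endoplasmic reticulum folding enzyme gene, fell 1.71-fold (-0.77 ± 0.14, 0.0391) and PNN, which encodes a splicing-associated protein, 1.44-fold (-0.53 ± 0.1, 0.0391), both in all 7 lines. The remaining called genes, named only after their values were seen, were GALNT16, HLA-DQB1, IGSF10 and SRPX, higher, and ADI1, lower. MAPT (ENSG00000186868) lies on chromosome 17 from 45894382 to 46028334.

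CDKN1A, often used as a marker of deacetylase inhibition, did not pass the test with SAHA. It had a log2 change of 0.56 (adjusted p = 0.393) and VIM of 0.62 (0.526), both above 0 in all 7 lines. With no filter on low counts both passed. For SAHA vs control: CDKN1A then had an adjusted p of 0.0115 (0.0115 to 1 over all alternatives). The same for SAHA vs control: VIM gave 1.9e-05 (1.9e-05 to 1). MYC had -0.13 (0.875), CDH1 -0.24 (0.827), KRT19 0.39 (0.623), ZEB1 -0.17 (0.849), GATA6 -0.12 (0.925), EP300 -0.10 (0.856), CREBBP -0.33 (0.472), HDAC1 0.09 (0.818), HDAC2 -0.07 (0.891) and HDAC3 0.07 (0.889). In total 11 of 15805 genes were called with SAHA, 8 up and 3 down, with 1385 at an unadjusted p under 0.05. The count was 196 (172 up, 24 down) with no filter on low counts and 46 (40 up, 6 down) with the DESeq2 Wald test. It was 0 without Capan-2 (edgeR, 855 at an unadjusted p under 0.05), 1 without Capan-1, 2 without Colo357, PaTu-S, MIA PaCa-2 or PaTu-T, and 12 without PANC1. Of the 6 genes named by rule, FKBP11 and PNN were lost without any single line (adjusted p 0.0541 to 0.18 and 0.082 to 0.442), TUBA1A and APLP1 without any but PANC1 (up to 0.346 for both), MAPT without 5 lines (up to 0.185) and CYFIP2 without 4 (up to 0.0842).

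Cell cycle genes were called lower with SAHA as groups only with the preset correlation between genes. In G2/M, 38 of 39 genes had a change below 0 (median -0.23), and in S phase 37 of 40 (median -0.20), with camera adjusted p of 1.92e-12 and 5.07e-11, and an adjusted p of 0.27 for each with an estimated correlation. Bromodomain readers (median -0.17, adjusted p = 2.04e-05) and MYC targets (median -0.15, 1.73e-05) were also called lower. Neuronal genes were called higher, with 12 of 13 above 0 (median 0.33, adjusted p = 0.00237), as were MHC class I genes (median 0.21, 0.00367), interferon genes (median 0.20, 0.00624) and the basal-like signature (median 0.44, 0.0326). No member of these lists passed over all genes, and 5 MHC class I genes, 1 interferon gene and 1 neuronal gene passed adjusted over the list alone. With an estimated correlation none of the 27 lists was called: the adjusted p was 0.27 for bromodomain readers and neuronal genes, 0.528 for MYC targets and interferon genes, 0.465 for MHC class I and 0.433 for the basal-like signature. Interferon genes were not called without Colo357 (0.0904) or PaTu-S (0.0606), nor the basal-like signature without Colo357 (0.376), PaTu-S (0.147), MIA PaCa-2 (0.119), PANC1 (0.143) or PaTu-T (0.0825). The other 19 lists had adjusted p from 0.0875 (acetylation genes) to 0.871 (epithelial, histone, acinar and housekeeping genes), among them 0.246 for mesenchymal genes, 0.344 for the classical signature and 0.393 for mucins.

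SAHA and A485 were then set against each other within lines, since they act on deacetylases and acetyltransferases. ABCA12, a lipid transporter gene, was 6.75-fold higher with SAHA than with A485 (log2 difference 2.75 ± 0.28, adjusted p = 1.7e-05), CD22 6.57-fold (2.72 ± 0.37, 0.000181), ACOX2, a peroxisomal oxidase gene, 6.35-fold (2.67 ± 0.36, 0.00014) and FLRT3, an adhesion protein gene, 5.75-fold (2.52 ± 0.33, 0.000126). CREB3L3, KRT15, UNC5B and ACSM3 were 4.08- to 5.39-fold higher, with CREB3L3 filtered out without Colo357. CDKN1A was 2.66-fold higher (1.41 ± 0.2, 0.000189) and KRT19 2.52-fold higher (1.33 ± 0.22, 0.000601). All of these were higher in 7 of 7 lines, but in lines that hardly expressed a gene the direction rested on very few counts. The lowest CPM over lines was 0.064 with A485 and 0.0744 with SAHA for UNC5B. It was 0.064 and 0.149 for ABCA12 and for KRT19. For ACSM3, CD22 and CREB3L3 it was 0 with A485 and at most 0.0851 with SAHA. COCH was 3.35-fold lower with SAHA (-1.74 ± 0.23, 0.00014), EGR1 1.95-fold lower (-0.97 ± 0.15, 0.000451) and IL27RA, a cytokine receptor gene, 2.34-fold lower (-1.23 ± 0.18, 0.000289), in all 7 lines. EFCAB2, STOX1, ICA1L, ATF5 and HMGN2P17 were 1.95- to 2.23-fold lower; HMGN2P17 is a processed pseudogene, so its reads may belong to its parent gene.

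Of the other genes named by rule, CREBBP (-0.59, adjusted p = 0.00553) and EP300 (-0.42, 0.0336) were lower with SAHA than with A485, and MYC (0.69, 0.0275) and CDH1 (0.84, 0.0494) higher. The EP300 call ended without any single line but Capan-1 (up to 0.123), the CDH1 call without any but PaTu-T (up to 0.115) and the MYC call without Colo357 (0.0635), PaTu-S (0.0991), MIA PaCa-2 (0.105) or PaTu-T (0.0624). VIM (0.77, 0.0855), HDAC1, HDAC2, HDAC3, ZEB1 and GATA6 did not pass. In all, 1438 genes differed, 1126 higher and 312 lower with SAHA, and 465 and 197 of them did so in all 7 lines. The count was 715 without PaTu-S, 799 without Capan-2 and 471 without both RPMI lines, where ICA1L (adjusted p = 0.0976), ATF5 (0.0507), CDH1 (0.185), CCNE2 (0.102) and GTSE1 (0.127) were not called, among others, and CD22 was filtered out. It was 0 with no replicate block (edgeR, 131 at an unadjusted p under 0.05) and 707 with only the 14 libraries compared. With the GC trend removed, chosen after seeing the data, it was 2161.

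Of the 10 lists called lower with A485, 8 were called higher with SAHA than with A485, and MYC targets (median 0.09, adjusted p = 0.152) and blood and endothelial genes (0.0521) were not. Both comparisons use the same 7 A485 libraries with opposite sign, so a list lower with A485 would tend to be higher here even if SAHA changed nothing. The classical signature had 19 of 26 genes higher (24 adjusted over the list alone), led by CEACAM5 (log2 difference 3.39 ± 0.38), and cholesterol synthesis 15 of 25 (20 adjusted over the list alone), led by INSIG1 (0.74 ± 0.1) and HMGCS1 (0.84 ± 0.12). Among basal-like genes 5 of 14 were higher (8 higher and 1 lower adjusted over the list alone), and mesenchymal genes had 7 of 20 higher (8 adjusted over the list alone), with TGFBI at 1.48 and FN1, the fibronectin gene, at 1.43. Epithelial genes had 7 of 30 higher (8 adjusted over the list alone), mucins 4 of 9 (5), efflux transporters 4 of 12 (4), neuronal genes 2 of 13 (4) and quasi-mesenchymal genes 2 of 15 (3), with the counts adjusted over the list alone in parentheses. YAP and TAZ targets had 3 higher and 2 lower of 22 (4 and 2). Lower with SAHA were bromodomain readers (3 of 15, and 6 adjusted over the list alone), led by BRPF3 (-0.83), acetylation genes (4 lower and 2 higher of 26, and 7 and 2), the S phase gene CCNE2 (-0.61) and the G2/M gene GTSE1 (-0.39), with 0 genes of either list passing adjusted over the list alone. Camera called these 14 lists. With an estimated correlation the adjusted p was 0.0145 for cholesterol synthesis and for basal-like genes, 0.0539 for the classical signature, mesenchymal genes and efflux transporters, 0.116 for mucins, 0.127 for bromodomain readers, 0.129 for neuronal and quasi-mesenchymal genes, 0.224 for acetylation genes, 0.235 for epithelial genes, 0.366 for YAP and TAZ targets and 0.471 for G2/M, and it was higher still for S phase. CCNE2 and GTSE1 were each not called without any of 3 single lines, at adjusted p up to 0.118 and 0.172 without PaTu-S. The other 13 lists had adjusted p from 0.0521 to 0.985 (p53 targets).

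Across 15325 genes, the mean changes with A485 and with SAHA correlated at r = 0.155 (genes are not independent replicates). Both changes were taken against the same 7 controls, and simulated unchanged groups set against those controls gave r from 0.483 to 0.509 (median 0.499 over 20 simulations). With no shared control, the median r over 70 splits of the lines was -0.016, from -0.155 to 0.0513. Signs were the same for 57.2% of genes, against 66.7% in the simulations. Of the called genes, 1 rose and 0 fell with both treatments in the edgeR tests, and no value for unchanged groups with shared controls was computed for this overlap.

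The control libraries were compared between the E and M line sets. VIM, the gene of the mesenchymal filament protein vimentin, averaged 4880 ± 3360 CPM (SD, n = 3) in M lines and 11.3 ± 15.1 CPM (SD, n = 4) in E lines (adjusted p = 0.0435), and BNC2, a zinc finger gene, 11 ± 2.39 against 0.0751 ± 0.0877 CPM (0.047). CDH1 averaged 8.99 ± 4.63 CPM in M lines and 699 ± 376 in E lines (77.8-fold lower, adjusted p = 0.0283). The epithelial splicing regulator ESRP1 averaged 1.64 ± 1.23 against 303 ± 121 CPM (0.0278), the transcription factor gene ELF3 0.752 ± 0.414 against 186 ± 88.3 (0.0176), the protease inhibitor gene SPINT1 1.52 ± 0.59 against 277 ± 114 (0.0164) and the tight junction gene TJP3 0.936 ± 0.216 against 30.2 ± 7.08 (0.0204). SLPI, LAD1, C1orf116, TMEM30B and ANKRD22 were also lower in M lines. GIRGL had no count in M lines, which makes it at least 41.7-fold lower against a floor of 3 counts per library. S100A14 and GPR35 had 1 count in the 3 M libraries together, against means of 23.5 ± 10.2 and 15 ± 7.94 CPM in E lines. VIM (ENSG00000026025) lies on chromosome 10 from 17228259 to 17237593.

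Other genes named by rule did not pass between the sets: GATA6 had a log2 difference of M minus E of -6.71 (adjusted p = 0.141), ZEB1 of 3.30 (0.356), KRT19 of -2.05 (0.646), CDKN1A of -1.46 (0.467), MYC of -0.02 (0.989), EP300 of -0.51 (0.667), CREBBP of -0.57 (0.641), HDAC1 of 0.11 (0.928), HDAC2 of 0.54 (0.587) and HDAC3 of 0.54 (0.391). Of 15177 genes, 66 differed, 2 higher and 64 lower in M lines. Both higher calls, VIM and BNC2, were lost at a mean count of 10 or more (0 higher, 22 lower) and with the GC trend removed, an alternative chosen after seeing the data (0 higher, 59 lower), whereas the DESeq2 Wald test called 288 higher and 859 lower. All 66 had no overlap between the sets, as had 14.6% of all tested genes against 5.71% by chance. The count was 0 without MIA PaCa-2 (edgeR, 2363 at an unadjusted p under 0.05), 0 without PANC1 (1883), 4 without Capan-2, 11 without Capan-1, 19 without PaTu-S, 32 without PaTu-T and 113 without Colo357, so every named call ended without at least 1 line. Capan-1 and Capan-2, both E lines, were grown in RPMI and all M lines in DMEM, so medium and line set partly coincide. Without both RPMI lines edgeR called 0 genes, with 1528 at an unadjusted p under 0.05, so no named call was kept. Mean total counts per line were higher in E than in M lines on average, without passing the test (two-sided exact permutation p = 0.0857).

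**Figure D3:**
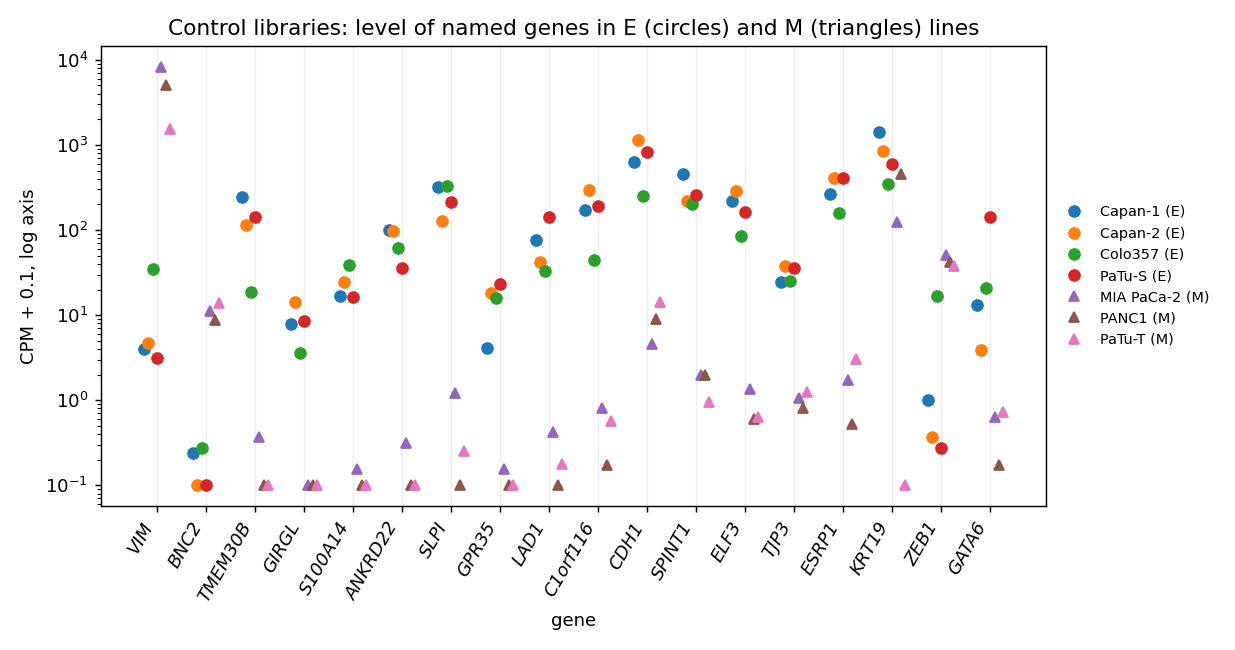
CPM plus 0.1 on a log axis in the 7 control libraries for named genes; circles are the 4 E lines and triangles the 3 M lines, 1 library each. VIM lies above all E lines in the 3 M lines, and CDH1 below them.

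Gene groups also differed between the control libraries of the sets, in calls that were all lost with an estimated correlation. Epithelial junction and keratin genes had 29 of 30 members lower in M lines (median -4.59), 9 of them called (24 adjusted over the list alone, adjusted p = 4.74e-38, and adjusted p = 0.0942 with an estimated correlation). The classical signature was lower in 26 of 26 genes, none called over all genes and 22 adjusted over the list alone (adjusted p = 3.92e-18, and adjusted p = 0.278 with an estimated correlation), with a median of -8.56, or -8.28 with the 2 genes without counts in M lines at their bound. Mucins were lower in 8 of 9 genes, with none called over all genes and 7 adjusted over the list alone (4.86e-07, and adjusted p = 0.0667 with an estimated correlation; median -5.87, or -5.44 with 1 gene at its bound). Interferon genes (median -1.41, 2 adjusted over the list alone, 3.17e-05), basal-like genes (2 adjusted over the list alone, 0.000505), polyadenylated histone genes (0.0441) and MHC class I genes (0.0441) were also called lower. Higher in M lines were mesenchymal genes (median 1.15; VIM, and 2 adjusted over the list alone, 0.00475), neuronal genes (median 1.75; 4 of 12 adjusted over the list alone, 0.00788), metallothioneins (0.0354) and hypoxia genes (0.0441). With an estimated correlation the adjusted p was 0.617 for interferon genes, 0.345 for basal-like and neuronal genes, 0.347 for histone and mesenchymal genes, 0.752 for MHC class I, 0.501 for metallothioneins and 0.672 for hypoxia genes. Single lines ended the calls of mesenchymal genes (without PaTu-S, 0.0555) and neuronal genes (without MIA PaCa-2, 0.0618), and of histone genes (up to 0.154), MHC class I (up to 0.581), metallothioneins (up to 0.111) and hypoxia genes (up to 0.564). The other 16 lists had adjusted p from 0.0777 (acinar and endocrine genes) to 0.907 (S phase).

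Whether the treatment effects differ between the line sets was tested by the interaction. CDH1 fell with A485 by a mean log2 ratio of -2.49 ± 1.05 (SD, n = 3) in M lines and -0.57 ± 0.16 (SD, n = 4) in E lines, without overlap, and the difference did not pass the test. CDH1 held 82 to 180 counts in the M controls against 4443 to 17299 in the E controls, so its M ratios lie nearer the floor. Of all tested genes, 4.5% had no overlap between the sets for this effect, against 5.71% by chance. For the A485 effect, M lines minus E lines: CDH1 had -1.57 with an adjusted p of 0.769, which was 0.00183 without PaTu-T and ran from 4.15e-05 (no filter on low counts) to 1 over all alternatives. For the A485 effect, M lines minus E lines: KRT19 had a difference of -1.16 (adjusted p = 0.584, and 0.0123 with no filter on low counts to 1 over all alternatives). The other reported genes named by rule had adjusted p of 1 for both treatments. For A485 edgeR called 0 of 15805 genes, with 597 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0685. With no filter on low counts edgeR called 85 (17 up, 68 down). DESeq2 called 15 and limma-voom 0, and edgeR called 8 without MIA PaCa-2 and 1 without PaTu-T. For SAHA edgeR called 0 genes, with 314 at an unadjusted p under 0.05, and 8 with no filter on low counts, while DESeq2 and limma-voom called 0.

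Some gene lists differed between the line sets in these effects, and a single call was kept with an estimated correlation. The A485 effect was lower in M than in E lines for epithelial junction and keratin genes (median -0.04, mean -0.41, 4 adjusted over the list alone, adjusted p = 0.00769), basal-like genes (11 of 14 below 0, 0.0283), NF-kappaB genes (median -0.30, 0.0283), interferon genes (median -0.26, 0.0376) and YAP and TAZ targets (median -0.18, 0.0408), and higher for cholesterol synthesis (19 of 25 above 0, median 0.14, 0.0335). With an estimated correlation the adjusted p was 0.655 for interferon genes and 0.432 for the other 5. The SAHA effect was lower in M lines for the classical signature (19 of 26 below 0, 0.0338), YAP and TAZ targets (19 of 22 below 0, median -0.39, 1.56e-06) and efflux transporters (median -0.23, 0.0278). It was higher for cholesterol synthesis (24 of 25 above 0, median 0.24, 1.08e-06), MYC targets (31 of 33 above 0, median 0.20, 0.000153) and the unfolded protein response (median 0.18, 0.00505). With an estimated correlation the adjusted p was 0.0302 for YAP and TAZ targets, 0.0693 for cholesterol synthesis, 0.328 for efflux transporters and 0.978 for the other 3. The other lists had adjusted p from 0.0825 to 0.971 for A485 and from 0.304 to 0.975 for SAHA. Without MIA PaCa-2 the adjusted p was 0.33 for the A485 effect on epithelial genes, and for the SAHA effect 0.933 on the classical signature, 0.0581 on MYC targets and 0.0581 on the unfolded protein response. Single lines also ended the A485 calls of basal-like genes (up to 0.36), interferon genes (up to 0.942), NF-kappaB genes (up to 0.252), cholesterol synthesis (up to 0.254) and YAP and TAZ targets (up to 0.227), and the SAHA calls of MYC targets (without PaTu-S, 0.0838) and efflux transporters (up to 0.327).

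The size of the response to A485 was 0.657 in Colo357, 0.651 in PaTu-S, 0.585 in MIA PaCa-2, 0.56 in Capan-2, 0.555 in Capan-1, 0.551 in PaTu-T and 0.536 in PANC1, as a root mean square log2 ratio. E lines averaged 0.606 ± 0.0555 (SD, n = 4) and M lines 0.557 ± 0.025 (SD, n = 3; two-sided exact permutation p = 0.286, where 0.0286 is the smallest possible). With SAHA, MIA PaCa-2 had 0.798 and the other lines 0.356 to 0.548. E lines averaged 0.495 ± 0.0391 and M lines 0.557 ± 0.224 (exact permutation p = 0.686). The M minus E difference of 0.0618 was 0.0172 with the GC trend removed, and without MIA PaCa-2 it was -0.0585, with an M mean of 0.436 (exact permutation p = 0.467). Without PANC1 it was 0.162 (exact permutation p = 0.133). All of these alternatives were chosen after the data were seen. A485 gave the larger response in 6 of 7 lines, by a mean of 0.063 ± 0.131 (SD; two-sided exact sign-flip permutation p = 0.25). Without MIA PaCa-2, left out after the data were seen, the mean was 0.11 and A485 gave the larger response in 6 of 6 lines (exact sign-flip permutation p = 0.0312, the smallest that 6 lines can give). With 1 library per line and condition, these sizes include the noise between libraries.

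**Figure D4:**
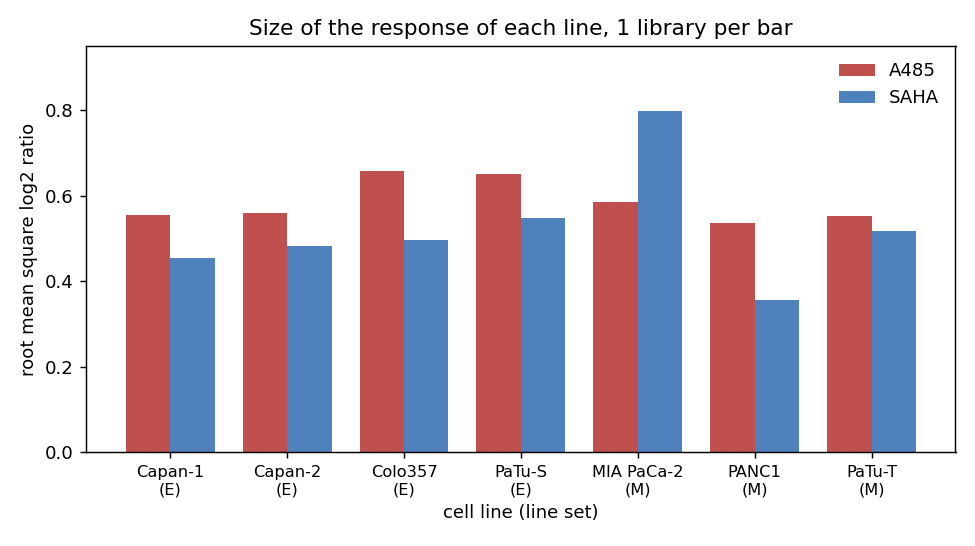
Root mean square log2 ratio of treated over control for each line, 1 library per bar, with A485 in red and SAHA in blue. MIA PaCa-2 has the tallest SAHA bar at 0.798, and the A485 bars lie between 0.536 and 0.657.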

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

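The GC test of the SAHA library of MIA PaCa-2 was chosen only after the result was seen. The line sets, the gene lists, the rule that names genes and the swaps and splits of labels were chosen before the data were examined, whereas the depth and correlation tests of that library were set after the pattern was noticed and before their results were seen.

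Single lines lay apart from the other 6 for several genes. With A485, SHISA4 had a log2 ratio of 3.45 in PaTu-S (nearest other line 1.1) and COCH, the cochlin gene, of 2.29 in PaTu-S (0.96). HDAC2 had 0.49 in Capan-1 (0.09), and AGR2, a secretory folding factor gene, 1.01 in PaTu-T (-1.27), against falls in the other 6 lines. The PaTu-T control held 0 CPM of AGR2, and the lowest value over lines with A485 was 0.128 CPM. This rise therefore lies at the floor and does not show an opposite response. With SAHA, CYFIP2 had 1.67 in MIA PaCa-2 (1.07), CDH1 -1.85 in PaTu-T (-0.52) and VIM 3.07 in Capan-2 (1.1). Between SAHA and A485, EP300 had 0.32 in Capan-1 (-0.4), HDAC3 0.62 in MIA PaCa-2 (0), the epithelial differentiation gene SCEL 5.66 in PaTu-S (2.38), CCNE2 -1.89 in MIA PaCa-2 (-0.96) and GTSE1 -0.90 in PaTu-S (-0.44). The apoptosis gene BMF had -1.94 (1.01) and TGFB2 -0.80 (0.91) in PaTu-T, and PECAM1 3.51 in Capan-1 (1.19). The median of the classical signature with SAHA was -1.19 in MIA PaCa-2 (-0.14). Of 235 groups of 7 lines examined, 16 held such a value, and chance flags about 1 in 20 groups, which is 11.8 here.

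Gene lists whose treatment effect differed between M and E lines form the other set. With an estimated correlation none of the A485 lists and 1 of the SAHA lists, YAP and TAZ targets (adjusted p = 0.0302), was called. For A485 with the preset correlation these were epithelial junction and keratin genes (adjusted p = 0.00769), basal-like genes (0.0283), NF-kappaB genes (0.0283), interferon genes (0.0376), cholesterol synthesis (0.0335) and YAP and TAZ targets (0.0408). For SAHA with the preset correlation these were the classical signature (0.0338), MYC targets (0.000153), cholesterol synthesis (1.08e-06), the unfolded protein response (0.00505), drug efflux transporters (0.0278) and YAP and TAZ targets (1.56e-06). Across alternatives the adjusted p ran from 1.88e-08 to 0.942 for the A485 lists and from 4.83e-08 to 0.983 for the SAHA lists. Chance cannot be excluded for the number of lists. With A485, 12 of the 35 splits of the lines into 4 and 3 gave 6 lists or more (real 6, highest other 11), and with SAHA 9 of 35 did (real 6, highest other 10). For single genes edgeR called 0 for A485 (DESeq2 15, limma-voom 0) and 0 for SAHA (DESeq2 0, limma-voom 0), so all 35 of 35 splits gave as many by construction (highest other 2 for each), which decides nothing. At an unadjusted p under 0.05, 18 of 35 splits gave as many as the 597 genes for A485 (highest other 1491) and 22 of 35 as many as the 314 for SAHA (highest other 1731), so chance cannot be excluded.

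For the called genes with A485, between SAHA and A485 and in the control libraries, no other swap or split of labels gave as many. Only the real labels, 1 of 64 swaps of labels within lines, gave 640 genes with A485 (highest other 241) and 1438 between SAHA and A485 (highest other 492). In the control libraries 1 of 35 splits, the real one, gave 66 genes (highest other 1). The E and M sets follow how these lines are commonly described, so that split was not an arbitrary one. A description as epithelial or mesenchymal-like already implies differences in such genes. The test of that split therefore adds no independent support. A share of 1 of 64 or 1 of 35 is the smallest that these tests can give. The 2 tests by swaps make chance unlikely and do not exclude it. With SAHA, 1 of 64 swaps, the real one, gave 11 called genes (highest other 2), which again makes chance unlikely and does not exclude it. For the 1385 genes at an unadjusted p under 0.05, 6 of 64 swaps gave as many (highest other 2172), so chance cannot be excluded there. Without 1 line the count of 11 became 0 (Capan-2; edgeR, 855 at an unadjusted p under 0.05), 1 (Capan-1) or 2 (Colo357, PaTu-S, MIA PaCa-2 or PaTu-T), and 12 without PANC1. For the number of lists called, chance cannot be excluded: 5 of 64 swaps gave 12 or more with A485 (highest other 13), 7 of 64 gave 8 or more with SAHA (highest other 11), and 7 of 35 splits gave 11 or more in the control libraries (highest other 13).

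The SAHA library of MIA PaCa-2 lay farther from its control than those of the other lines, at a response size of 0.798 against at most 0.548. That library also had the fewest genes detected (20575, next 22372), the lowest TMM factor (0.857) and the highest share of counts in its top 10 genes (10.4%). A difference in its quality other than those tested below stays open. Its change correlated with GC content at r = 0.49. Such a trend was not particular to it, since PaTu-T with SAHA had r = -0.47 at a response size of 0.517. After removal of the GC trend the response size of MIA PaCa-2 was 0.696 (at most 0.548 in the other lines, SD 0.0634), which argues against GC content bias as the whole cause. With the counts of every library redrawn, with replacement, at a total of 11518316 it was 0.838 (at most 0.619, SD 0.0572). The redraw added counting noise to all libraries, as in PANC1, which went from 0.356 to 0.448. MIA PaCa-2 still stood apart at equal totals, which argues against lower depth as the whole cause. With the GC trend removed, the change of MIA PaCa-2 correlated with the mean change of the other 6 lines at r = 0.193 across genes. This lies inside the 0.0537 to 0.382 of those lines, so a larger form of the shared change stays open. The label gives SAHA at 0.5 µM for this line and the protocol 0.05 µM for long treatment. Whether the dose bears on the size of this response was not tested. No biological explanation was tested.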

How the results depend on the processing

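The GC correction, alone and without MIA PaCa-2, the scaling on housekeeping genes and leaving out single lines for the response size were chosen only after the data were seen. Of 153 called values of named genes, 153 kept direction and call with DESeq2 size factors, 149 with no filter on low counts, 145 at a mean count of 10 or more, 149 with DESeq2, 147 with limma-voom and 144 with the GC trend removed. Of those that could be tested, 78 of 150 did without the 2 lines in RPMI, 100 of 129 with only the 14 libraries compared and 0 of 138 with no replicate block. Leaving out single lines kept from 103 of 151 (without PaTu-S) to 128 of 151 (without Colo357). With the GC trend removed and MIA PaCa-2 left out, 3 of 6 SAHA calls were kept (APLP1, MAPT and TUBA1A lost), and scaled on housekeeping genes 53 of 56 A485 calls (FAM83A, UCA1 and IL32 lost). None reversed in any of these. Values that became called with no filter were CDKN1A and VIM with SAHA, VIM between SAHA and A485, CDH1 and KRT19 in the A485 difference between line sets and VIM in the SAHA difference. GATA6 became called with A485 by limma-voom and in the control libraries by DESeq2, ZEB1 in the control libraries without Colo357, and CDH1 in the A485 difference without PaTu-T.

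With no filter on low counts the count of genes was 1283 for A485, 196 for SAHA, 85 and 8 for the M minus E difference in the A485 and SAHA effects, and 120 in the control libraries, and at a mean count of 10 or more 22 in the control libraries. Without the 2 lines in RPMI, where fewer samples remain, it was 215 for A485, 471 for SAHA against A485, 0 for SAHA (edgeR, 742 at an unadjusted p under 0.05) and 0 in the control libraries (1528). With no replicate block edgeR called 0 for A485 (55), 0 for SAHA (22) and 0 for SAHA against A485 (131). With only the 14 libraries compared it was 1 for the A485 difference between line sets, 2 for SAHA and 707 for SAHA against A485. With the GC trend removed it was 1116 for A485, 635 of them shared with the 640, and 2161 for SAHA against A485. At a fold of 2 or more it was 283, 7 and 542 for A485, SAHA and SAHA against A485. Limma-voom called 998 for A485, and the DESeq2 Wald test 46 for SAHA, 15 for the A485 difference between line sets and 1147 in the control libraries. Except for smaller sample sets, the cause was not tested.

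Leaving out each line in turn gave 326 (without PaTu-S) to 690 (without MIA PaCa-2) genes for A485, with 364 without Capan-2. SAHA gave 0 (without Capan-2; edgeR, 855 at an unadjusted p under 0.05) to 12 (without PANC1), with 1 without Capan-1 and 2 without each of Colo357, PaTu-S, MIA PaCa-2 and PaTu-T. SAHA against A485 gave 715 (without PaTu-S) to 1435 (without MIA PaCa-2), with 799 without Capan-2. The A485 difference between line sets gave 0 to 8 (without MIA PaCa-2), with 1 without PaTu-T. The control libraries gave 0 (without MIA PaCa-2 or PANC1; 2363 and 1883 at an unadjusted p under 0.05) to 113 (without Colo357), with 4, 11, 19 and 32 without Capan-2, Capan-1, PaTu-S and PaTu-T.

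With an estimated correlation 4 lists were called for A485, 0 for SAHA, 0 in the control libraries, 0 for the A485 difference between line sets and 1 for the SAHA difference. Fry called 0 for SAHA, 2 in the control libraries and 0 for either difference. Classical signature, mucin and cholesterol synthesis genes were called lower with A485 under each of 12 alternatives.

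The M minus E difference in response size to A485 reversed from -0.0486 to 0.0131 at a prior count of 0.5 (exact permutation p = 0.771), and without single lines ran from -0.0653 (Capan-1) to -0.0313 (Colo357). That to SAHA ran from -0.0585, reversed from 0.0618 (without MIA PaCa-2), to 0.162 (without PANC1). The correlation of the A485 and SAHA changes was -0.016 with no shared control and 0.102 at a mean count of 100 or more. The former also set the A485 change of some lines against the SAHA change of others, so the cause was not tested. Libraries held 11518316 to 21824683 counts, and how far depth limits the calls was not tested.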

Other observations

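The GC test of the share of rises was chosen only after the result was seen, and the first 2 patterns below were noticed in the data before their other tests were set.

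Genes lower with A485 may have fallen most in the lines that expressed them most. Over the 538 falling genes, the median correlation across 7 lines between the change and the level in the SAHA library, which shares no counts with either side of the change, was -0.393, and it was below 0 for 74% of them. For genes not called it was -0.086, and below 0 for 56.9%. This argues against chance values of the shared control library. For the 128 falling genes with 100 or more counts in every SAHA library it was -0.113 and below 0 for 56.2%, against -0.069 and 56% for genes not called with as many counts, so counts near the floor in lines that lack the gene cannot be told apart from a dependence on level: the value lies between the bounds of -0.1 and -0.2 set for this test.

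More genes were lower than higher with A485, with 15.9% of the 640 called genes higher. Scaled on housekeeping genes the share was 23.1% of 553, and with the GC trend removed 25.5% of 1116. Both argue against scaling between libraries or GC content bias as the whole cause. An acetyltransferase inhibitor may lower more genes than it raises, which is a hypothesis found and tested on the same data.

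Changes of different lines were only weakly alike. Over 21 pairs of lines the correlation across 15325 genes had a median of 0.19 (-0.09 to 0.33) for A485 and 0.10 (-0.22 to 0.27) for SAHA. Genes are not independent replicates, and each change rests on 1 library per line and condition. The GC trend was not removed here, and in the lowest pairs the changes correlated with GC content in opposite directions. These were Capan-1 (r = -0.29) and Colo357 (0.42) with A485, and MIA PaCa-2 (0.49) and PaTu-T (-0.47) with SAHA. How far GC content or noise lowered the correlations was not tested, so they do not show that the lines respond differently.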
